A study of Mus musculus with 8 samples.

How the data were processed

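The series measured total RNA of liver on the A and B arrays of the Affymetrix mouse 430 set. Per the labels, livers were frozen in liquid nitrogen, RNA was extracted on columns and biotin-labelled cRNA was prepared. The authors deposited 1 intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes; its version, detection calls and scan settings are not given in the sources used here. The 4 arrays of each table had 2% trimmed mean signals near 1500, so the deposited scaling was kept. Scaling to a common mean removes overall differences in yield, and it does not correct a loss of signal towards the 5' end of transcripts. The labels name 1 pool per category and do not say whether both array types received the same labelled RNA. With 1 pool per category, no spread between replicate pools was measured. The residual of the fit is the genotype by sex contrast, moderated towards a prior over probe sets. SEs therefore measure departure from additive effects of genotype and sex, which includes any real difference between the sexes in the genotype effect. The p-value of a probe set sets its genotype or sex difference against that SE. The p-values of gene lists are computed over genes and measure no spread between pools or mice.

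Intensities were converted to log2 without an offset. Control probe sets, 64 on each array, were left out, and probe sets were kept whose mean log2 intensity reached the median of their table, which left 11313 on the A array and 11256 on the B array. The platform annotation gave 1 symbol for 20380 probe sets of the A array, several for 691 and none for 1555; on the B array these numbers were 14661, 245 and 7605. Symbols were updated by Entrez identifier through a RefSeq gene table of assembly GRCm38.p6, which matched 20351 and 14486 and changed 20 and 39. No build is named for the files, so no coordinates are given. A probe set with several symbols names no gene here. Where a gene had several probe sets, the brightest on the A array was used, or the brightest on the B array where the A array kept none.

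Each table was fitted alone with limma 3.58.1 in R 4.3.3, with genotype and sex as terms, which left 1 residual degree of freedom, and with an intensity trend in the empirical Bayes step. The prior had 3.89 degrees of freedom on the A array and 4.91 on the B array. Benjamini-Hochberg adjustment was applied within a table at 0.05. The genotype by sex interaction had no residual degree of freedom, and differences within a sex are given as values. Of 37 gene lists fixed before the data were examined, 31 with at least 5 kept genes were tested with cameraPR on z-scores at a preset correlation of 0.01 and again with a correlation estimated from the residual contrast. Negative estimates were set to 0, and an estimate under 0.01 makes the repeat less strict than the preset test. Medians within a sex were set against 10000 random lists of equal size matched on intensity. The lists of sex chromosome, T and NK cell, B cell, erythroid, pancreas and fat, and alpha-1-antitrypsin genes kept 4, 2, 4, 2, 2 and 2 genes and were not tested.

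Named genes were chosen by a rule set before the data were examined: per comparison and direction, the 12 largest differences past the threshold with equal direction in both strata, filled up with genes at least 2-fold changed in both strata in order of the smaller difference; up to 4 genes per list with the smallest p; the members of the alpha-1-antitrypsin and sex chromosome lists; and Rgs16. Genes named beyond this rule are said to be so or are named for a count.

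The fit was tested on simulated data with 200 changed probe sets in each of 25 draws. The moderated spread of each probe set was first taken as the truth, and false calls then made up 21.8% of genotype calls and 18.2% of sex calls on the A array and 15.6% and 17.0% on the B array. Spreads drawn from the fitted prior, and the larger number of draws, were added after that result was seen. With these, the genotype test on the A array (11313 probe sets) called 1.73% of 2-fold, 61.1% of 4-fold and 85.0% of 8-fold changes, and on the B array (11256 probe sets) 0.776%, 22.4% and 52.7%. False calls made up 7.22% of calls on the A array and 9.69% on the B array for genotype, and 10.1% and 14.0% of calls for sex. Every one of these shares lies above the nominal 0.05 of the adjustment, so the test of single probe sets is liberal. The list test called 100% of lists of 20 probe sets shifted by 0.5 on the A array for genotype and 1.4% of unchanged ones. These simulations hold no correlation between genes.

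Alternatives were quantile normalization, an offset or a floor at the 25th percentile, no filter or a filter at the 75th percentile, no second term, other variance priors, an adjusted p under 0.1, a 1.5-fold threshold and each pool left out in turn. Leaving out a pool also left out the second term, since 3 arrays leave no residual degree of freedom with both, and the lone pool is then assumed to vary like the others. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.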

Results

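Liver RNA of PiZ mice, which carry a human transgene for the Z form of alpha-1-antitrypsin (ATZ) expressed in hepatocytes, was compared with that of wild-type (Wt) C57Bl/6 mice by microarray. ATZ is a misfolding variant of a serum protease inhibitor that is retained in the endoplasmic reticulum of hepatocytes. Livers of 4 mice aged 3 to 4 months made up a pool, with 1 pool for each combination of genotype and sex. Each combination had an A array and a B array of the Affymetrix mouse 430 set, which gives 8 samples. The A array held 22690 probe sets and the B array 22575. Differences within a sex had no replicate, and genotype was tested over 2 PiZ and 2 Wt pools, so n = 2 stands behind each mean log2 difference. Its SE rests on how the difference varied between the sexes and on the prior, not on replicate pools of a category. The number of arrays limits the precision. The median signal was 604.55 to 659.45 on the A arrays and 935.8 to 998.8 on the B arrays.

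Xist and Eif2s3y followed the sex labels on the A array. The genotype labels could not be checked in this way, since the probe annotation names no probe set for the human transgene. Xist, the X-inactivation RNA, had a signal of 7347 in Wt females and 6300 in PiZ females against 748.5 in Wt males and 798.8 in PiZ males, and the Y-linked Eif2s3y 970.4 and 1036.9 in males against 8.1 and 8.5 in females. Another Xist probe set read 21.6 and 32.1 in Wt and PiZ males against 5876 and 5174 in females. A further Xist probe set read 26.4 and 25.6 in males against 583 and 567 in females. On the B array the Y-linked Uty read 463.7 and 394.9 in males against 41.8 and 128.1 in females by 1 of its 2 probe sets, while Eif2s3y read 359.2 in PiZ females, 97.8 in Wt females and 364.5 and 376.2 in males. The Wt male pool stood apart from the other pools. Its mean Spearman correlation across probe sets with the other arrays was 0.930 on the A array, where the other pools had 0.949 to 0.951, and 0.866 on the B array, where they had 0.876 to 0.882. The ratio of 3' to 5' signal of beta-actin was 3.87 in Wt males and 1.20 to 1.30 in the other pools on the A array, and 3.21 against 1.35 to 1.42 on the B array. The same ratio of the added bacterial control thr was 9.83 in Wt males against 1.86 to 2.06 in the other pools on the A array.

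**Figure D1:**
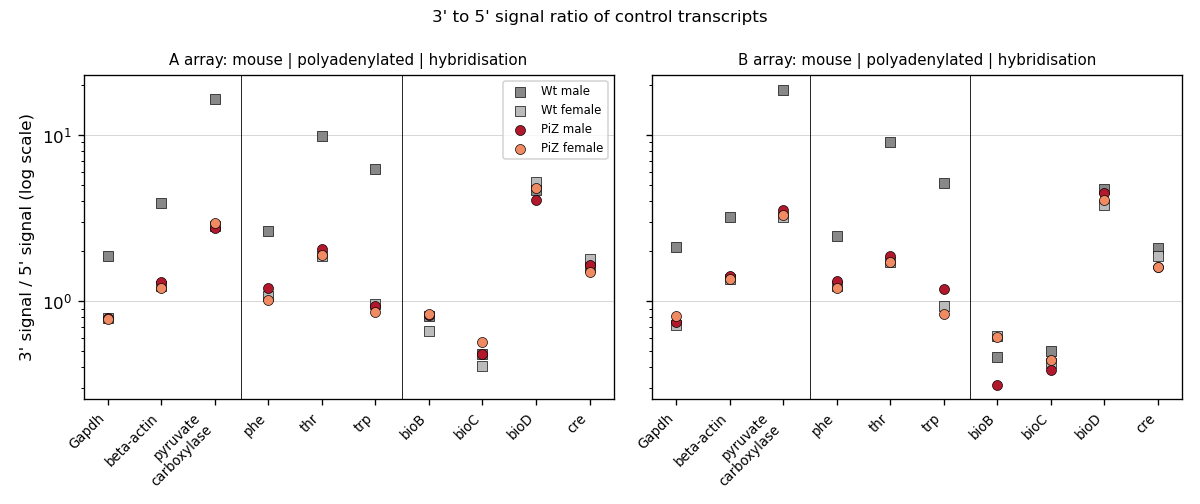
Ratio of 3' to 5' signal (log axis, no unit) of control transcripts on the A and B arrays, 1 point per pool. The mouse transcripts drawn and the polyadenylated controls phe, thr and trp were highest in the Wt male pool, and over all hybridisation controls (bioB, bioC, bioD and cre) 4 of 16 ratios were. Over all mouse controls 6 of 10 ratios were, and 18S RNA (highest in PiZ females) and transferrin receptor (highest in PiZ males) are not drawn.

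The comparison of PiZ with Wt livers asked which transcripts differ in liver that expresses the transgene. The genes with the largest differences of equal direction in both sexes included Col3a1, a fibrillar collagen, at 1360 to 1367 in the Wt pools and 8593 to 9222 in the PiZ pools (log2 difference 2.71, SE 0.20), and Cbr3, a carbonyl reductase, at 187.1 to 243.9 against 1852 to 2048 (3.19, SE 0.29). Lgals3, a galectin of macrophages and other cells, differed by 2.57 and Gstm3, a glutathione S-transferase, by 2.17. Ccnd1, which encodes cyclin D1, differed by 1.69. Lower in PiZ pools of both sexes were Sec14l4 (-2.57), the amino acid transporter subunit Slc3a1 (-2.31), Cyp17a1, a steroid hydroxylase (-2.01), the apolipoprotein Apoa4 (-1.82) and Pttg1 (-1.36, and -2.66 by another probe set).

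No single probe set passed the threshold. With limma and adjustment over 11313 probe sets of the A array, 0 had an adjusted p under 0.05 (smallest adjusted p = 0.0710), while 744 had an unadjusted p under 0.05 against 566 by chance, of which 507 were higher and 237 lower in PiZ. On the B array 0 of 11256 passed and 565 had an unadjusted p under 0.05 against 563 by chance. The probe set with that smallest adjusted p, 1 of 6 kept for the class I gene H2-D1, read 300.1 to 334.6 in Wt and 7297 to 9291 in PiZ pools (log2 difference 4.70), while the others for this gene had differences from -0.74 to 0.83; this gene was chosen after its values were seen. Quantile normalization gave 11 calls on the A array, among them Col3a1, Cbr3, Lgals3, Gstm3, Sec14l4, Pttg1 (by 1 of its probe sets) and Sparc. Without the Wt male pool 61 probe sets of the A array passed and 3 of the B array, and without the Wt female pool 801 and 13; these fits set a single Wt pool against both PiZ pools, with sex left out.

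On the A array 90 probe sets were at least 2-fold higher and 22 at least 2-fold lower in PiZ than in Wt pools in both sexes, and 18 differed by as much in opposite directions. On the B array these numbers were 67, 56 and 99, so that 99 opposite differences stood beside 123 of equal direction there. Across probe sets, the male and female differences correlated at 0.182 on the A array and 0.017 on the B array (Pearson). Mean differences between genotypes reached 2-fold for 306 probe sets on the A array and 536 on the B array. Setting PiZ males and Wt females against the other pools gave 155 and 499, so genotype stood out little on the B array. The balance on the B array depended on the processing, with 25 higher and 32 lower with an offset and 7 and 12 with a filter at the 75th percentile. With a pool left out, where the remaining pool of that genotype is shared, they were 118 and 218 without PiZ males, 98 and 271 without PiZ females, 223 and 102 without Wt males and 460 and 156 without Wt females. With 1 probe set per gene, 77 of 11649 genes were higher and 37 lower by at least 2-fold in both sexes. Further genes of this kind were the macrophage and epithelial gene Lyz1 (1.79), Sox4 (1.94), Cap1 (1.92) and Ly6d (3.70), whose signal of 80.1 in Wt females lay under the 25th percentile of its array (192.3), so that the size of its difference is not measurable there. Cbr3 in Wt males and, on the B array, Abcc4 in Wt males also lay under that percentile. On the B array Abcc4, an efflux transporter, differed by 2.55 and Abcd2 by -1.72. The 2 B array probe sets for Sox4 differed by -0.34 and 0.79. Without the Wt male pool, a choice made after the data were seen, males have no Wt reference and no count over both sexes exists. Both PiZ pools then differed from the Wt female pool at least 2-fold in the same direction for 197 probe sets of the A array and 325 of the B array, numbers that a shared reference raises and that do not compare with 112 and 123.

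**Figure D2:**
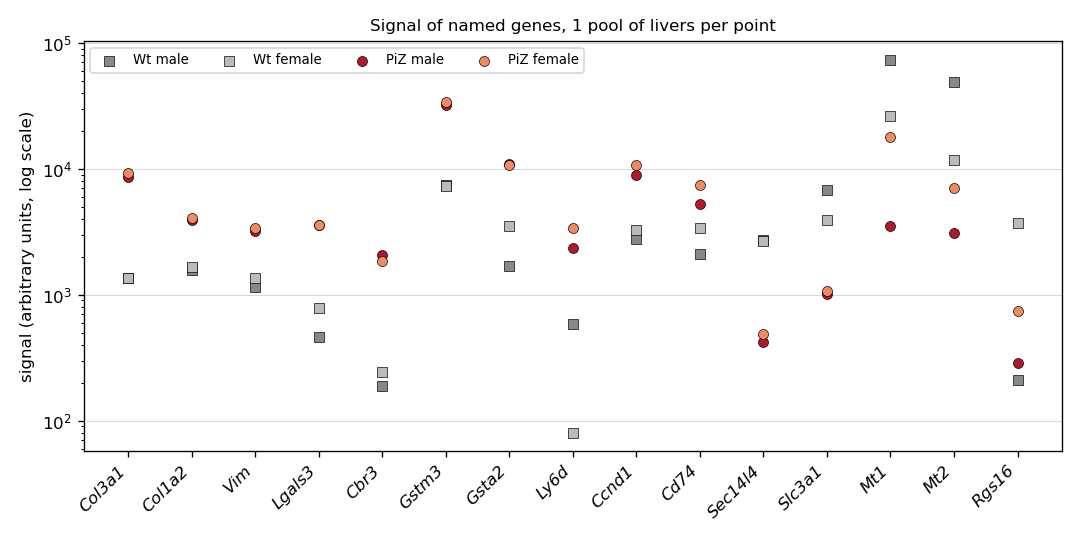
Signal (arbitrary units, log axis) of named genes in the 4 pools, 1 point per pool and no error bar because each category had a single pool. Col3a1 lay at 1360 to 1367 in Wt and 8593 to 9222 in PiZ pools, whereas Mt1 and Mt2 were highest in the Wt male pool and Rgs16 in the Wt female pool.

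Gene lists fixed before the data were examined moved together where single genes did not pass. The list test sets the genes of a list against the other genes, so its p-values, however small, measure no spread between pools or mice. Of 31 lists tested with limma's cameraPR, 17 passed, 12 higher and 5 lower in PiZ, and 10 passed with an estimated correlation between genes. Of these 10, only the class II (0.139), macrophage (0.155) and interferon lists (0.0714) had an estimate above the preset 0.01. For the others the repeat could not raise the unadjusted p and is no stricter check. Leaving out 1 pool, a choice made after the data were seen, reversed the direction of the test for some of the 17 lists. This was so for 2 without Wt males, 2 without Wt females, 1 without PiZ males and 0 without PiZ females. Other lists lost their call, as given per list below. Matrix and stellate cell genes rose most clearly: of 20 measured, 19 were higher in PiZ and 8 at least 2-fold higher in both sexes, with a median log2 difference of 0.95 (adjusted p = 8e-17). Adjusted over the list alone 13 passed, and 0 passed over all genes. These included Vim, the intermediate filament vimentin (1.41), the collagens Col1a2 (1.31) and Col4a2 (1.49), and Col3a1. The median was 0.86 in males and 1.05 in females, and 1.11 without the Wt male pool.

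Genes of a list of oncofetal and tumour-associated transcripts rose as well (9 of 9 higher, median 0.76, adjusted p = 9.34e-11). That list held 19 genes, of which only these 9 were kept. Besides Cbr3 and Ly6d, the annexin Anxa2 was at 1.39 and the lipase Lpl at 1.60, and 6 of the 9 passed when adjusted over the list alone against 0 over all genes. Glutathione and NRF2 target genes rose (16 of 23 higher, median 0.39, adjusted p = 4.13e-05), with Gsta2 at 2.15 and Gsta4 at 1.04, and 5, among them the sulfiredoxin Srxn1, passed adjusted over the list alone against 0 over all genes. The metallothioneins Mt1 and Mt2 of the same list were at -2.48 and -2.35, with the Wt male pool at 73300 for Mt1 and the other pools at 3514 to 26420.

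Cell cycle genes rose (12 of 13 higher, median 0.48, adjusted p = 5.81e-05), with 13 of the 30 genes of that list kept. Ccnd1 and the replication factor Mcm2 (1.42) passed adjusted over the list alone, against 0 over all genes, and Cdc20 was at 0.73. Immediate early and heat shock genes rose (10 of 13 higher, median 0.66, adjusted p = 0.000101), with the chaperones Hsph1 at 1.25, Dnajb1 at 1.31 by 1 probe set and 0.10 by another, and Hspa8 at 0.81, of which 1, Hsph1, passed adjusted over the list alone and 0 over all genes. That list lost its call without the Wt female pool (median 0.12) and without the PiZ male pool (0.23). Its median was 0.64 without the Wt male and 0.74 without the PiZ female pool.

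Markers of some immune cells rose. MHC class II genes were higher in 5 of 5 cases (median 0.98, adjusted p = 4.62e-06), with Cd74 at 1.23 and H2-Eb1 at 1.09, and 4 passed adjusted over the list alone against 0 over all genes. H2-Aa was at 0.98, at 1.81 by another A array probe set and at 0.40 on the B array, with -0.25 in males there. A haplotype difference, as raised below for H2-D1, was not tested for the H2 genes of this list. Macrophage and Kupffer cell genes were higher in 14 of 20 cases (median 0.48, adjusted p = 3.33e-05, and adjusted p = 0.0405 with an estimated correlation), led by Lyz2 (1.22), Cd52 (1.22), Ctss (0.95) and Cd14 (0.89), with 5 genes past the threshold adjusted over the list alone and 0 over all genes. Of this list 6 genes were lower, and its median was 0.20 without the Wt male pool (adjusted p = 0.0337) and 0.72 without the Wt female pool. Interferon response genes rose (9 of 12 higher, median 0.24, adjusted p = 0.00440, and adjusted p = 0.0414 with an estimated correlation), with Usp18 at 1.26 and alone past the threshold adjusted over the list alone, and lost the call without the PiZ female pool (adjusted p = 0.271). NF-kB target genes (9 of 11 higher, median 0.32, adjusted p = 0.0111) had an adjusted p = 0.0541 with an estimated correlation. The NF-kB list lost its call without the Wt female pool (median 0.18) and without the PiZ female pool (0.43). Of its genes Tnfaip3 was at 1.23, while Cxcl1 was at -1.32, and at -0.55 and -1.29 by B array probe sets. Sinusoidal endothelial markers (9 of 13 higher, median 0.23, adjusted p = 0.0384) had an adjusted p = 0.0935 with an estimated correlation and were past the threshold under 4 of 10 alternatives, with medians at percentiles 94.1 in males and 91.0 in females of random matched lists. Neutrophil markers did not pass (6 genes, adjusted p = 0.886).

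Genes of the endoplasmic reticulum stress response were higher in PiZ in 21 of 23 cases (median 0.21, adjusted p = 0.00105), with an adjusted p = 0.231 with an estimated correlation. Manf was at 0.69 in males and 1.31 in females, Creld2 at 1.26, Asns at 0.72 and Trib3 at 0.66. The median was 0.06 in males and 0.42 in females, and 0.45 without the Wt male pool, whose beta-actin ratio was 3.87. Without the Wt female pool the list's median was -0.070 and it lost the call (adjusted p = 0.562), and without the PiZ male pool it also lost the call (adjusted p = 0.1003). Genes of protein folding and degradation in the endoplasmic reticulum (21 genes, median 0.05, adjusted p = 0.143, with -0.15 in males and 0.24 in females) and of autophagy and lysosomes (22 genes, median 0.04, adjusted p = 0.856) did not pass, but the former passed under quantile normalization (adjusted p = 0.0311) and without the Wt male pool (median 0.18, adjusted p = 0.000757). Among the autophagy genes the autophagy receptor Sqstm1 was at 0.67, and at 0.026 by a B array probe set, and the kinase Ulk1 at -0.67.

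Acute phase genes were lower in 21 of 23 cases (median -0.59, adjusted p = 3.33e-05), with an adjusted p = 0.261 with an estimated correlation. The median was -1.42 in males, where the Wt pool had the beta-actin ratio of 3.87, and -0.002 in females, and without the Wt male pool the list did not pass (median -0.086, adjusted p = 0.584). Apcs, the serum amyloid P component, read 48050 in Wt males and 8523 to 16050 in the other pools. Genes of cholesterol synthesis were lower in 16 of 18 cases (median -0.23, adjusted p = 0.00427, and adjusted p = 0.261 with an estimated correlation), with medians of -0.54 in males and -0.08 in females and with Hmgcs1 at -0.73 and Fdft1 at -0.79. Their other probe sets differed less, by -0.43, -0.33 and -0.28 for Hmgcs1 and -0.33 for Fdft1. The call of the cholesterol list was lost without the PiZ male pool (median -0.12).

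Genes of secreted hepatocyte proteins were lower in 19 of 20 cases (median -0.20, adjusted p = 0.00115, and adjusted p = 0.261 with an estimated correlation), and this call was lost under quantile normalization (median -0.03, adjusted p = 0.652) and without the PiZ male pool (adjusted p = 0.0547). Its medians of -0.31 in males and -0.06 in females lay at percentiles 7.22 and 38.7 of random matched lists, within their range. Cytochrome P450 and related genes were lower in 12 of 17 cases (median -0.11, adjusted p = 0.0298, and adjusted p = 0.0402 with an estimated correlation), with Cyp2c37 at -1.02, and under quantile normalization the median was 0.015 while the test pointed down (adjusted p = 0.637); without the Wt female or the PiZ male pool the adjusted p was 0.456 and without the sex term 0.0601. Circadian clock genes were higher in 12 of 16 cases (median 0.28, adjusted p = 0.0203, and adjusted p = 0.231 with an estimated correlation), with Wee1 at 1.21, Per2 at 0.81 and Nr1d1 at -0.73, and without the Wt male pool the median was -0.029 (adjusted p = 0.822). The circadian list was past the threshold under 4 of 10 alternatives. The list of bile acid synthesis and transport did not pass (median -0.17, adjusted p = 0.307), but did without the Wt male pool (-0.27, adjusted p = 0.00589). Of its genes 8 were higher and 11 lower in PiZ (SD 0.81). The bile acid hydroxylase Cyp8b1 was at -0.98 and the uptake transporter Slc10a1 at -0.62, while Abcc4, named above as higher in PiZ in both sexes, also belongs to this list. The lists of male-biased genes, p53 and apoptosis, hepatocyte transcription factors, oxidative phosphorylation, fatty acid synthesis, fatty acid oxidation, cholangiocyte and progenitor markers, urea and amino acid metabolism, and gluconeogenesis did not pass either, with adjusted p values from 0.0552 to 0.856. Of these, fatty acid synthesis (median -0.39, adjusted p = 0.00107), urea and amino acid metabolism (-0.16, 0.0218), hepatocyte transcription factors (-0.18, 0.0465) and male-biased genes (0.57, 0.00624) passed without the Wt male pool, where sex and genotype are mixed. The p53 list passed without a filter (adjusted p = 0.00264). Male-biased genes passed as lower in PiZ with an offset (0.0498), with the mean over probe sets (0.0338), and without the Wt female (0.000324) or PiZ male pool (8.66e-06).

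**Figure D3:**
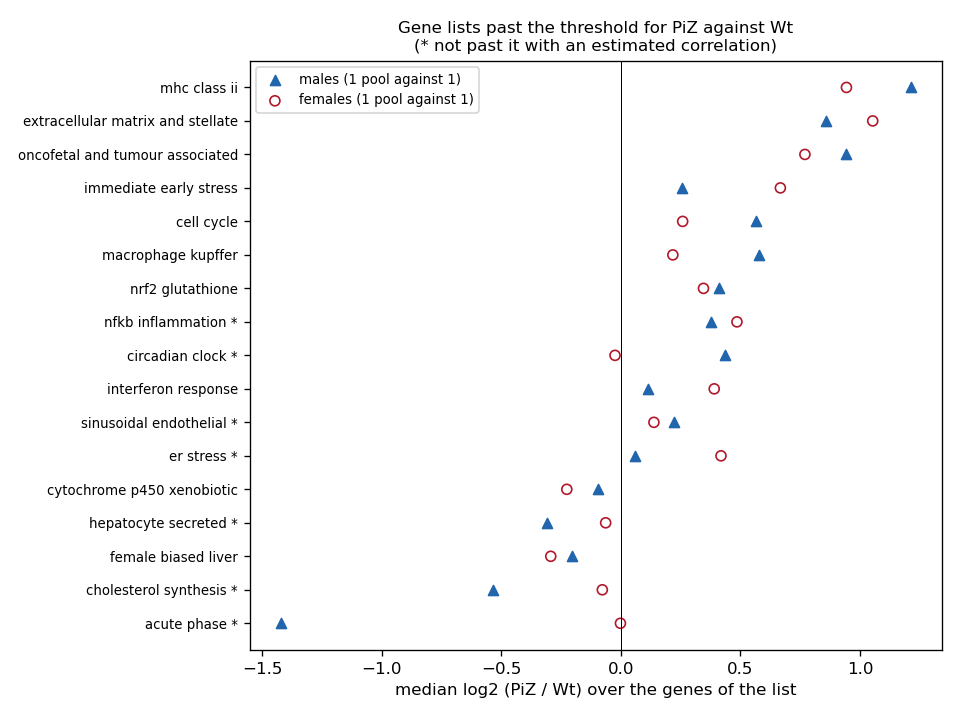
Median log2 ratio of PiZ to Wt over the genes of each list that passed, in males (triangles) and females (circles), each 1 pool against 1. The matrix and stellate list stood at 0.86 and 1.05, the acute phase list at -1.42 in males and -0.002 in females.

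Genes reported in earlier work on ATZ did not pass as a list (10 genes, median -0.09, adjusted p = 0.771). Of these genes 4 were higher and 6 lower (SD 1.11), and 3 had an unadjusted limma p under 0.05. The list test asks for a shared direction, so it cannot decide on changes of opposite direction among its members. Mt1 and Mt2, which were highest in Wt males, belong to this list. Rgs16, a regulator of G protein signalling, read 3694 in Wt females, 744.8 in PiZ females, 287.1 in PiZ males and 211.6 in Wt males, so that PiZ minus Wt was 0.44 in males and -2.31 in females, and 1.13 without the Wt female pool. The mouse alpha-1-antitrypsin genes had log2 differences of -0.18 for Serpina1b, which was 0.031 under quantile normalization, and -0.34 for Serpina1c, and neither passed. The Serpina1c signal was the highest of the Wt female A array (77160). Whether such signals were saturated was not tested.

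The comparison of males with females served as the other axis of the design. Of the named genes that passed, Sult2a2, a sulfotransferase, was lowest in males relative to females (log2 difference -6.53, SE 0.23, adjusted p = 0.0153), followed by the cytochrome Cyp2b9 (-4.80, adjusted p = 0.0162), Cyp17a1 (-3.32), the thioesterase Acot3 (-3.22) and Xist (-3.14), these with an adjusted p = 0.0393. The Xist value is that of the brightest of its probe sets, which also had the highest signal in males. Nat8 (4.61, SE 0.30, adjusted p = 0.0393) and the fatty acid elongase Elovl3 (3.15, SE 0.22, adjusted p = 0.0416) were higher in males. All of them had this direction in both genotypes. With limma 10 probe sets of the A array passed, 2 higher and 8 lower in males, while 644 had an unadjusted p under 0.05. On the B array 0 passed and 541 had an unadjusted p under 0.05. Quantile normalization called 9 higher and 12 lower on the A array, while without a filter or without an intensity trend 3 passed, 0 of them higher in males, so that Nat8 and Elovl3 did not. Without the PiZ male pool 171 passed on the A array, without the Wt male pool 7, without the PiZ female pool 5 and without the Wt female pool 4. On simulated data 10.1% or 18.2% of such calls were false, depending on the spread assumed.

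Lists of sex-biased liver genes, which were fixed for this contrast and hold several of the genes above, moved as blocks. Female-biased genes were lower in males in 12 of 12 cases (median -2.02, adjusted p = 2.52e-21), with 11 past the threshold adjusted over the list alone and 3 over all genes, Cyp2b13 at -5.24 and Fmo2 at -2.23. Male-biased genes were higher in 14 of 14 cases (median 2.14, adjusted p = 7.85e-20), with 11 past the threshold adjusted over the list alone and 1 over all genes. Among them Cyp4a12a was at 5.64, Cyp2d9 at 3.45, C6 at 2.62 and Cyp7b1 at 2.54, and Hsd3b5 at 6.52 with an SE of 1.35. The sizes for Cyp4a12a (81.7 in Wt females), Hsd3b5 (13.2 in PiZ females), Cyp2b13 (95.6 in PiZ males), Sult2a2 (176.9 in Wt males) and Nat8 (169.2 and 176.7 in females) are differences against signals under the 25th percentile of the array and not measured folds. Fatty acid synthesis genes were lower in males (13 of 15, median -0.37, adjusted p = 8.3e-05) and immediate early genes higher (10 of 13, median 0.42, adjusted p = 0.00896), the latter with an adjusted p = 0.290 without the Wt female pool and 0.613 without the PiZ male pool. In all 11 of 31 lists passed, and these 4 did so with an estimated correlation. Their estimates, from -0.083 to -0.034, were negative and set to 0, so for them this is no stricter check. With a pool left out, the direction of the test reversed for 2 of the 11 without the Wt male pool and 1 without the PiZ female pool. It reversed for 0 without the Wt female or the PiZ male pool, but further lists lost their call. The lists of endoplasmic reticulum stress (median 0.48, higher in males) and circadian (-0.32) and urea cycle genes (-0.08, both lower) passed and had an adjusted p = 0.135 with an estimated correlation. Macrophage (-0.36), class II (-0.26) and cytochrome P450 genes (-0.098) were lower in males and acute phase genes (0.34) higher, and had adjusted p = 0.113, 0.118, 0.0507 and 0.470 with an estimated correlation. Without the Wt male pool the medians were -0.023 for macrophage (adjusted p = 0.514), 0.073 for class II (0.514) and -0.071 for circadian genes (0.574), and without the PiZ female pool 0.11 for class II genes (0.891). Without the Wt female pool the stress, urea cycle and cytochrome P450 lists did not pass (adjusted p = 0.174, 0.179 and 0.249). The acute phase median was 0.79 in Wt and -0.21 in PiZ pools, and -0.17 without the Wt male pool (adjusted p = 0.00135), whose beta-actin ratio was 3.87. Female-biased genes were also lower in PiZ than in Wt pools (9 of 12, median -0.22, adjusted p = 0.0298), with Cyp17a1 and Abcd2 past the threshold adjusted over the list alone; without the Wt female pool the median was 0.78 and without the PiZ male pool 0.50, fits in which genotype and sex are mixed, and without the sex term the call was lost (adjusted p = 0.484).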

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

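Of the tests below, those on agreement between array types, acute phase genes and added controls were chosen after the result was seen.

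The 3' to 5' ratios of several control transcripts, which enter no comparison, were higher in the Wt male pool than in the other pools. For beta-actin the ratio was 3.87 on the A array and 3.21 on the B array, and for the bacterial control thr 9.83 and 9.04. A fault of a single hybridisation is argued against by the deviations of the Wt male pool over 100 probe sets present on both array types, which correlated at 0.698 between them. The polyadenylated bacterial controls, which standard protocols add before labelling, had their highest ratio in Wt males in 14 of 16 cases, and the hybridisation controls, added after it, in 4 of 16 (4 if pools were alike), so although the labels do not say when they were added, a candidate source is the labelling reaction of that sample. These ratios are not separate draws, since dap, lys, phe and the hybridisation controls were each read by more than 1 pair of probe sets. Both array types may also hold the same labelled RNA. For 1 dap pair the 5' signals on the A array were as weak as 22.8 to 33.5. Poorer RNA in the Wt male pool stays open, since of 4 ratios of the further mouse controls, pyruvate carboxylase and transferrin receptor, 2 were highest there. Pyruvate carboxylase was at 16.4 in Wt males against 2.7 to 2.9 in the other pools on the A array, and at 18.7 against 3.2 to 3.5 on the B array. Transferrin receptor was highest in PiZ males on both, with 5' signals as weak as 83 to 294.4 on the A array and 727.4 to 1377 on the B array. A biological response in those mice stays open as untested: acute phase genes exceeded the highest other pool by a median log2 of 0.711, but that list was picked because it was already seen to be high there.

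PiZ minus Wt differed in direction between males and females for 18 probe sets of the A array and 99 of the B array, each at least 2-fold. Genes of cholangiocytes and liver progenitors (5 genes) had a median of -0.46 in males and 0.52 in females. Acute phase genes were higher in males than females in Wt pools (median 0.79) and lower in PiZ pools (-0.21). Set against random matched lists, the median over genes of the male minus the female difference lay at percentile 30.7 for the cholangiocyte and progenitor genes, within the range of chance, and at percentile 0 for the acute phase genes. The latter was not particular to that list. The endoplasmic reticulum stress, cholesterol synthesis and male-biased lists also lay at percentile 0, and the circadian list at 99.95. Each of these values rests on single pools, so no difference between sexes or genotypes was tested over replicates.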

How the results depend on the processing

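Leaving out pools for 2-fold counts, lists and single genes was chosen after the data were seen. Leaving out a pool also mixes sex into genotype or genotype into sex, by construction. PiZ against Wt gave 0 calls on the A array in the main setting, 11 with quantile normalization, 1 without the sex term, 1 at an adjusted p under 0.1 and 0 to 801 with a pool left out, and on the B array 0 to 13 with a pool left out. Males against females gave 10 calls on the A array, 21 with quantile normalization, 3 without a filter, 3 without an intensity trend and 4 to 171 with a pool left out. On the B array it gave 0, 2 with the 75th percentile filter, 3 without the genotype term and 0 to 173 with a pool left out. Of the 10 sex calls 10 were kept under quantile normalization, offset, floor and robust priors. The number of probe sets at least 2-fold different in both sexes, 112 on the A array and 123 on the B array, became 73 and 57 with an offset, 722 and 987 without a filter, 52 and 19 with the 75th percentile filter, and 396 and 551 at 1.5-fold. With a pool left out, 1 sex lacks a pair and both pools of 1 genotype are set against the same single pool, which favours equal direction; these counts, 145 to 623 and 325 to 616, are another quantity. With an estimated correlation 10 of 17 genotype lists and 4 of 11 sex lists passed. With a pool left out, 11 to 20 genotype lists and 8 to 12 sex lists passed. The lists of matrix, oncofetal, class II, macrophage, glutathione and cell cycle genes passed under each of 10 alternatives. Among these lists, the alternative of an estimated correlation was a stricter check only for class II and macrophage genes.

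For PiZ against Wt, the direction of the test turned for acute phase genes without the Wt male pool (median -0.086 with the test pointing up, and -1.14 to -0.086 over the pools left out), for circadian genes without the Wt male pool (-0.029 to 0.47), for stress genes of the endoplasmic reticulum without the Wt female pool (-0.070 to 0.45), and for female-biased genes without the Wt female (0.78) or PiZ male pool (0.50, with -1.62 as the lowest). For males against females it turned for acute phase genes without the Wt male pool (-0.17 to 0.84) and for class II genes without the Wt male (0.073) or PiZ female pool (-0.87 to 0.11). Of the named genes Serpina1b turned to 0.031 with quantile normalization and Rgs16 without the Wt female pool (-3.00 to 1.13). The cause was not tested. Without a filter, probe sets near background enter, and opposite 2-fold differences rose from 18 to 483 on the A array, so weak signal limits fold counts.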

Other observations

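The tests on composition and on the Wt male pool were chosen after the result was seen.

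Markers of other cell types did not all move alike in PiZ livers: the mean log2 difference was 0.97 (SD 0.69 over 20 genes) for the matrix and stellate list, 0.87 (SD 0.36 over 5) for class II, 0.42 (SD 0.48 over 20) for macrophages and 0.25 (SD 0.39 over 13) for sinusoidal endothelium. The matrix mean lay 0.713 above the endothelial mean (two-sided permutation test over genes, p = 0.00189). The class II mean lay 0.620 above it (exact permutation p = 0.00689). These distances argue against an equal log2 rise of these lists, but the means were known when the tests were written. Genes are also not independent replicates. A lower share of hepatocytes is not excluded, since it need not raise every marker by the same log2 amount. For the macrophage list an equal rise stays open, since its distance of 0.166 (permutation p = 0.301, 95% bootstrap interval -0.12 to 0.44) neither excludes nor shows it. The Wt male pool as sole source is argued against, since without it the medians of the matrix, macrophage and class II lists lay at percentiles 100, 99.0 and 99.9 of random matched lists. A response of stellate and other cells to the transgene may fit and was not tested further, and as the labels name no second line, the design does not part line and transgene.

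Large differences of equal direction in both sexes may in part mark a different strain background of the PiZ line. For H2-D1, 1 probe set differed by 4.70 while the median of the other 5 was -0.446, which a haplotype or sequence difference read by that probe set would give. Of 63 genes of the A array at least 2-fold different in both sexes, 9 lay within 10 annotated genes of another, against a median of 2 and a 95th percentile of 6 in random sets (permutation p = 0.0107), and 5 did so when pairs of the same name stem were left out (permutation p = 0.155), so a segment of another background stays open. These 5 were Sec14l4 (-2.57) with Gal3st1 (1.44) on 1 side and Tbc1d10a (-1.39) on the other, and the pair Capg (1.71) and Tmsb10 (1.49), named after their values were seen. The rest of the 9 were the collagen pairs Col3a1 with Col5a2 and Col4a1 with Col4a2, all genes of the matrix list that rose as a block.

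Genes measured by different probe sets on both array types gave little agreement: over 1459 genes, the log2 differences of PiZ and Wt correlated across genes at 0.109 (Pearson), those of males and females at 0.182, and of 5 genes at least 2-fold different in both sexes on the A array 2 had the same sign on the B array. Genes are not independent replicates.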
